A study of Rattus norvegicus with 44 samples.

How the data were processed

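Kidney cortex of male rats was collected at postnatal days 0, 5, 15 and 21 from whole litters, and 44 poly-A RNA libraries were sequenced, 1 per animal. Samples were grouped by the age and genotype in their labels, which gives 12 groups of 3 or 4 libraries. Replicate numbers follow the order of the records only. The animal numbers in the titles have no stated meaning and were used only in alternatives and to weigh explanations. The title of PND21_Homo replicate 1 has another prefix than the rest, and its number is also that of PND5_Het replicate 3. It was taken as a number of 100 and above by assumption.

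The authors deposited 1 table of FPKM per gene and library; their processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3, without the role of each. The deposited FPKM were checked against the gene lengths in the table. Every library's values became whole reads, within 0.01 read, when multiplied by gene length and a size particular to the library, in 100% of values. That size was 0.8327 to 1.105 times the reads counted, so a composition scaling was part of the values before deposit. The genome build is not given in the sources used here, and the labels describe both directional and non-directional libraries without saying which was made. Reads shared between close paralogs (the Klk1c, Hba, Cyp4a, Slco1a and RT1 families) cannot be parted in such a table.

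The reads counted per library ranged from 12686228 to 23329418, with a median of 14809000. Over 60 pairs of replicates, Pearson r of log2 values was 0.9626 to 0.9862, across genes, which are not independent replicates. The chi-square per degree of freedom between replicates was 6.597 to 59.83, so animals differed by more than counting error. The summed FPKM of a library ranged from 490497 to 718285.

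Genes were tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3) on log2(FPKM + 1). The model held 12 group means over all 44 libraries, with trended and robust empirical Bayes. Genes with FPKM of at least 1 in 3 or more libraries were kept, 16283 of 32545, of which 7209 were at 0 in every library. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and rose, fell and changed are used for these alone. Contrasts were Homo against WT, Het against WT and Homo against Het at each age and WT between adjacent ages, 15 in all, and an F test asked whether the difference between Homo and WT changed with age. Xdh was also tested with two-sided exact permutation tests of the difference of mean log2(FPKM + 1), adjusted over 12 comparisons.

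For gene lists, 893 gene entries in 40 lists were written from general knowledge. Of these 853 were matched to the table and 784 were tested. They cover nephron segments and cell types, purine and energy metabolism, injury, immunity, stress, and tissues that a dissected cortex can carry: erythroid and blood, adrenal, fat tissue, skeletal and smooth muscle, liver, and osmotic response and inner medulla. Each list was tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 40 lists. Of the lists past camera, the number past it with an estimated correlation was 0 of 13 in Homo against WT at PND0, 0 of 1 at PND5, 5 of 22 at PND15 and 8 of 24 at PND21. It was 2 of 14, 0 of 23 and 0 of 17 in the successive WT ages. Counts adjusted over the list alone are given beside those over all genes.

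The maturity score is the mean log2(FPKM + 1) of 500 genes minus that of 500 others, chosen as rising or falling by at least 1 log2 unit from PND0 to PND21 in Het libraries alone. Homo and WT scores were compared with two-sided exact permutation tests, adjusted over 4 ages. With 3 against 3 libraries the smallest p is 0.1.

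The genes named were set by rule. Xdh is always named. For Homo against WT the rule takes the 8 largest changes per direction among called genes with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between groups, and up to 4 called members per list by smallest p. It takes 3 per direction for the other genotype contrasts, 5 per direction between WT ages with up to 4 list members, and the 10 smallest p of the F test. Some genes that the rule takes are not reported here. Of groups of 3 against 3 libraries that do not differ, 10% show no overlap by chance. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined; a list of glucocorticoid target genes, the setting aside of libraries and a wider term for animal numbers came after.

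The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, TPM, division by median ratios, array weights, voom on the recovered reads, only the ages or groups compared, a term for animal numbers of 100 and above where both groups hold both kinds, 100 genes per direction in the score, and each library left out in turn. The method was tested on simulated counts with 100 genes changed per size. It recovered 93%, 88%, 92% and 86% of 2-fold changes at the sizes of PND0, PND5, PND15 and PND21, and called 10, 10, 5 and 10 unchanged genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Supplied gene names of the RefSeq annotation served for matching symbols only.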

Results

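RNA from the kidney cortex of male rats was sequenced at 4 ages, postnatal days (PND) 0, 5, 15 and 21, in animals labelled wild type (WT), heterozygous (Het) or homozygous (Homo) at Xdh, the gene of xanthine dehydrogenase, which makes urate in purine breakdown. The kind of Xdh allele is not given in the sources used here. The 44 libraries form 12 groups. At PND0 they hold 4 WT, 3 Het and 4 Homo animals, at PND5 3 WT, 4 Het and 4 Homo, at PND15 4 of each, and at PND21 3 WT, 4 Het and 3 Homo. The reads counted on genes, recovered from the table of FPKM (reads scaled by gene length and library size), ranged from 12686228 in PND0_WT replicate 4 to 23329418 in PND5_Het replicate 3, with a median of 14809000. The series title names the maturation of the kidney as its question, so the comparisons ask how genotype and age change the transcriptome of the developing cortex. Of 32545 genes, 16283 were tested. Means carry the SD over the libraries of a group.

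Xdh (ENSRNOG00000007081, chromosome 6, 25149235 to 25211494, minus strand, a protein coding gene; the genome build is not given in the sources used here) was measured in every library. In WT it was 2.84 ± 1.07 FPKM at PND0 (SD, n = 4), 4.18 ± 0.627 at PND5 (n = 3), 15.7 ± 1.88 at PND15 (n = 4) and 24.2 ± 1.68 at PND21 (n = 3). At PND5 Homo held 0.667 ± 0.344 (n = 4), 16% of WT, and at PND15 5.58 ± 2.2 (n = 4), 35.4% of WT. At PND21 Homo held 16 ± 2.32 (n = 3), 66.3% of WT. Het held 13.2 ± 3.43 (n = 4), 54.5% of WT. The mean of Homo thus lay above that of Het at PND21, the reverse of PND5 and PND15. This difference was 0.29 ± 0.61 log2 (SE, limma adjusted p = 0.752, two-sided exact permutation p = 0.2, adjusted over 12 tests 0.267). Homo libraries held 13.5, 16.6 and 18 FPKM and Het libraries 17.9, 9.7, 12.2 and 13. Xdh therefore did not separate Homo from Het at PND21. Het held 70.1% of WT at PND5 and 69.4% at PND15. Every Homo library lay below every WT library at these 3 ages, with a two-sided exact permutation p of 0.0286 at PND5, 0.0286 at PND15 and 0.1 at PND21, where 3 against 3 libraries cannot give less. Adjusted over 12 such tests these were 0.0686, 0.0686 and 0.171 (exact permutation tests). The limma adjusted p was 1, 0.0847 and 0.549, so Xdh was not called at any of these ages in the model of all libraries. The spread of Xdh in that model is shared by all groups. It takes in PND0, where the SD of Xdh was 10.5 FPKM in Homo and 14.4 in Het. It was called at all 3 with only the ages compared (adjusted p = 0.0212, 0.00352 and 0.0289) and with only the groups compared (adjusted p = 0.0277, 0.012 and 0.00823).

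At PND0, Xdh went against the labels. Of the libraries labelled Homo, replicate 1 held 0.727 FPKM, replicate 2 held 0.649, replicate 3 held 11.7 and replicate 4 held 22.5. Of the libraries labelled Het, replicate 1 held 1.87, replicate 2 held 26.8 and replicate 3 held 1.75. The libraries labelled WT held 2.29, 3.69, 3.78 and 1.6. The difference between libraries labelled Homo and WT was 0.54 ± 0.56 log2 (SE, limma adjusted p = 0.701; two-sided exact permutation p = 0.629, adjusted over 12 tests 0.755). Each direction drawn at PND0 therefore rests on labels that Xdh does not follow.

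**Figure D1:**
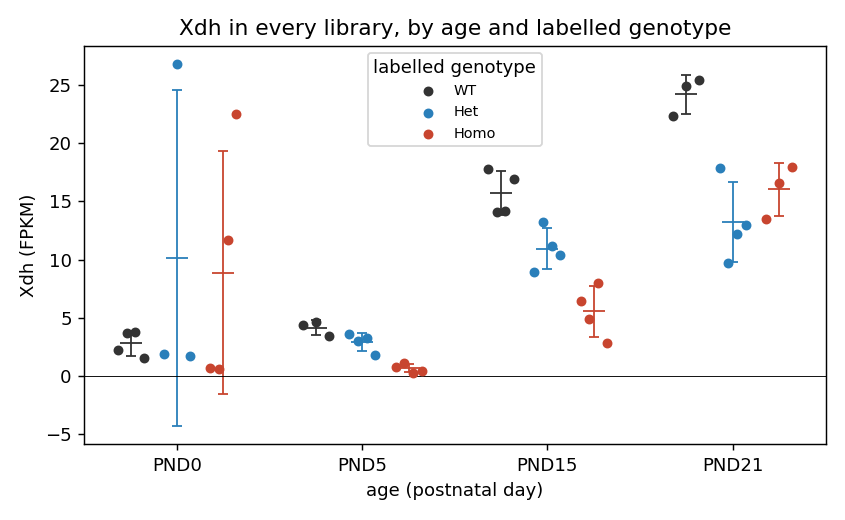
Xdh in FPKM (y axis) at each postnatal day (x axis) in every library, coloured by labelled genotype; points are libraries, horizontal bars are group means and vertical bars the SD, drawn in full even where they pass 0. At PND0 the libraries at 26.8, 22.5 and 11.7 FPKM are labelled Het, Homo and Homo, while at PND5 the Homo libraries average 0.667 FPKM and the WT libraries 4.18.

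The normal course was read from the WT libraries. Between PND0 and PND5 the genes of nephron progenitors and of the branching ureteric tip fell. Six2, a transcription factor that keeps nephron progenitors undifferentiated, went from 16.4 ± 4.84 FPKM (n = 4) to 0.664 ± 0.299 (n = 3), and Ret, the receptor of GDNF in the ureteric tip, from 5.82 ± 0.635 to 0.247 ± 0.112. Fgf20 was at 0 reads in the PND5 libraries and at least 17.4-fold lower (floor of 3 reads over the group). Of 25 progenitor and early nephron genes 13 fell and 1 rose (adjusted over the list alone 16 and 1, median -0.61 log2; camera adjusted p = 3.38e-12, adjusted p = 0.000241 with an estimated correlation), among them Eya1 and Gdnf at 0.16 and 0.192 times their PND0 level. Of 13 ureteric tip genes 6 fell and 0 rose (adjusted over the list alone 7 and 1; camera adjusted p = 6.22e-05, adjusted p = 0.029 with an estimated correlation). Proximal tubule transporters rose in 15 of 31 and fell in 0 (adjusted over the list alone 15 and 0; camera adjusted p = 1.4e-08, adjusted p = 0.306 with an estimated correlation). Slc5a2, the main glucose carrier of the proximal tubule, rose 2.1-fold and Aqp1, a water channel, 2.16-fold. Antigen presentation and interferon genes rose in 10 of 29 and fell in 0 (adjusted over the list alone 12 and 0; camera adjusted p = 1.4e-08, adjusted p = 0.202 with an estimated correlation). Cd74 stood at 59.8 ± 4.5 against 21.1 ± 3.08 FPKM.

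Among the 5 largest rises from PND0 to PND5 were Nox4, an oxidase of the proximal tubule, at 41.5 ± 2.25 FPKM (n = 3) against 7.54 ± 2.87 (n = 4; log2 difference 2.37 ± 0.2 SE, adjusted p = 1.22e-10), and Spink1, a protease inhibitor, at 9.44-fold. The other 3 were Dpt, Alox15 and Prima1, and the 5 largest falls were Six2, Spock2, Dlk1, Hmox1 and Ret. Hmox1, heme oxygenase, stood at 0.122 times its PND0 level, but its call was lost with only the ages compared (adjusted p = 0.057) and with only the groups compared (adjusted p = 0.0861). In all, 1923 genes changed, 1102 up and 821 down; the count was 823 without PND5_WT replicate 2, 1248 without PND5_WT replicate 1 and 1273 without PND0_WT replicate 2, 4121 with array weights and 1062 with only the groups compared. With every library rescaled to the same summed FPKM (TPM), 1786 genes were called and 43.5% of them rose.

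From PND5 to PND15 genes of tubule function rose and cell cycle genes fell. Proximal tubule transporters and endocytosis genes rose in 27 of 31 and fell in 0 (adjusted over the list alone 27 and 0, median 0.89 log2; camera adjusted p = 9.4e-16, adjusted p = 0.138 with an estimated correlation). Urate and organic anion transporters rose in 16 of 19 and fell in 1 (adjusted over the list alone 17 and 1; camera adjusted p = 1.55e-10, adjusted p = 0.0992 with an estimated correlation). Fatty acid oxidation genes in 20 of 28 and fell in 0 (adjusted over the list alone 21 and 0; camera adjusted p = 5.77e-10, adjusted p = 0.277 with an estimated correlation). Slc22a7, an organic anion carrier, rose 13.1-fold, Slc7a9, part of the cystine carrier, 2.27-fold, and Acadm, a dehydrogenase of fatty acid oxidation, 1.59-fold. Hnmt, which inactivates histamine, went from 0.747 ± 0.442 FPKM (n = 3) to 23.6 ± 3.32 (n = 4), and Egf, a growth factor made by the distal tubule, from 3.7 ± 1.32 to 38.9 ± 14.2. Cell cycle genes fell in 14 of 35 and rose in 0 (adjusted over the list alone 21 and 0; camera adjusted p = 3.56e-07, adjusted p = 0.501 with an estimated correlation). Aurka, a mitotic kinase, stood at 0.562 times its PND5 level. Afp, a protein of fetal liver, fell from 141 ± 49.5 to 5.66 ± 1.26 FPKM.

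Xdh rose 3.77-fold over this interval (log2 difference 1.69 ± 0.61 SE, adjusted p = 0.0367), but the call was lost without any 1 of the 7 libraries, with a pseudocount of 0.1 (log2 difference 1.89, adjusted p = 0.0665) and with TPM (1.71, adjusted p = 0.056). It was kept with array weights (adjusted p = 0.00135), voom (1.92, adjusted p = 0.0486), only the ages compared (adjusted p = 1.53e-05) and only the groups compared (adjusted p = 1.29e-05). In all, 4215 genes changed, 2119 up and 2096 down; with TPM 1458 rose and 2875 fell.

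From PND15 to PND21 genes of oxidative phosphorylation rose in 26 of 30 and fell in 0 (adjusted over the list alone 28 and 0, median 0.4 log2; camera adjusted p = 9.64e-15, adjusted p = 0.195 with an estimated correlation), 9 of them with TPM, beside a mitochondrial share of reads that went from 8.41 ± 0.828% to 10.7 ± 0.547%. Genes of glutathione and the NRF2 response rose in 13 of 27 and fell in 0 (adjusted over the list alone 16 and 0; camera adjusted p = 1.33e-08, adjusted p = 0.128 with an estimated correlation). Gclc, which limits glutathione synthesis, went from 332 ± 29.3 FPKM (n = 4) to 984 ± 298 (n = 3), and Osgin1 rose 3.23-fold. Erythroid genes rose in 7 of 12 and fell in 1 (adjusted over the list alone 9 and 1; camera adjusted p = 0.00056, adjusted p = 0.368 with an estimated correlation). Wnt9b and Wnt11, signals of the ureteric bud, fell to 0.0654 and 0.215 times their PND15 level. Dnase1 rose 6.29-fold and Slc51a, a bile acid and steroid carrier, 8.07-fold, both among the 5 largest rises. In all, 2786 genes changed, 1607 up and 1179 down. This split depended on the scaling: TPM moved the median of all genes by -0.2 log2 and called 5042 genes, 638 up and 4404 down. The count was 1486 without PND21_WT replicate 3 and 1843 without PND15_WT replicate 4.

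At PND0, libraries labelled Homo (n = 4) differed from libraries labelled WT (n = 4) in 57 genes, 18 higher and 39 lower. Gpx3, a secreted glutathione peroxidase of the proximal tubule, was higher, at 1910 ± 184 against 1190 ± 165 FPKM, as was Aqp7, a glycerol channel of the proximal tubule, at 35.9 ± 2.94 against 22.9 ± 3.3. Of 25 progenitor and early nephron genes 3 fell and 0 rose (adjusted over the list alone 9 and 0): Six2 at 9.18 ± 1.89 against 16.4 ± 4.84, Cited1, another progenitor marker, at 5.76 ± 1.28 against 11.1 ± 2.8, and Fgf20 at 1.03 ± 0.223 against 1.8 ± 0.465. This list passed camera (adjusted p = 2.37e-05; adjusted p = 0.0692 with an estimated correlation). Proximal tubule metabolism also passed camera with 0 members called (adjusted over the list alone 6 higher and 0 lower; median 0.34 log2, adjusted p = 2.11e-07; adjusted p = 0.341 with an estimated correlation), beside a mitochondrial share of reads of 7.31 ± 0.126% against 6.15 ± 0.403%. The superoxide and antioxidant list had Gpx3 alone called among 23 (adjusted over the list alone 5 and 0; camera adjusted p = 0.000129; adjusted p = 0.341 with an estimated correlation). Cell cycle genes had a median of -0.25 log2 with 0 of 35 called (adjusted over the list alone 0 and 0; camera adjusted p = 8.72e-05; adjusted p = 0.855 with an estimated correlation), and this median turned to 0.11 with the 3 libraries that went against their labels set aside, a setting chosen after seeing the data.

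Among the 8 largest rises at PND0 were also Clk1, Ctsl, Gatsl3, Pold4, Cryl1 and Cib1, and the 8 largest falls were Syt6, Klf10, Cited1, Six2, Mn1, Notch2, Frem2 and Siah1. With the 3 libraries set aside 21 genes were called, of which 6 were shared. Of the 18 named genes with a value 16 lost the call, Six2, Cited1, Fgf20 and Gpx3 included, while Aqp7 kept it. All 57 genes kept their direction in that fit. Homo held only replicates 1 and 2 there, so lost calls may also come from fewer libraries. With a term for animal numbers of 100 and above, also chosen after seeing the data, 12 genes were called. Six2 (limma adjusted p = 0.055), Cited1, Fgf20 and Gpx3 lost the call. At PND0 only Homo holds numbers on both sides of 100, so the term rests on its replicates 1 and 2 against 3 and 4. Homo against WT is then carried by Homo replicates 1 and 2, as with the setting aside, so the term is no separate check. With only the ages or only the groups compared 0 genes were called (2402 genes had an unadjusted p under 0.05 in the model of all libraries), voom on recovered reads called 103, array weights 456, and TPM 165, of them 21 up and 144 down. The count was 11 without PND0_WT replicate 2, 31 without WT replicate 3, 166 without WT replicate 4, 167 without Homo replicate 1, 25 without Homo replicate 3 and 2 without Homo replicate 4. Only Aqp7 among the genes named here was called in each of the 8 fits that left out 1 library.

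At PND5, Homo (n = 4) and WT (n = 3) libraries were separated by Xdh but by no gene in the test. limma called 0 genes, with 209 at an unadjusted p under 0.05, and voom called 0. These 209 are under 5% of the 16283 genes tested, the share that chance alone would give. The chi-square per degree of freedom between replicates reached 15.07 at PND5 and 59.83 at PND0. A spread shared by all groups can thus be too wide at PND5 and too narrow at PND0. A fit to the libraries of the groups compared called 4, a fit to the libraries of PND5 called 1 and the test without a filter called 2, and without PND5_WT replicate 2 the count was 1. Tubular injury genes had a median log2 difference of 0.01 over 31 members and proximal tubule metabolism genes 0 over 30. The fat tissue list, which a dissected kidney can carry, had a median of -0.75 log2 over 12 members, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.000115; adjusted p = 0.996 with an estimated correlation).

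At PND15 the cortex of Homo (n = 4) differed widely from WT (n = 4). Genes that injured tubule cells switch on rose in 24 of 31 and fell in 0 (adjusted over the list alone 26 and 0, median 1.45 log2; camera adjusted p = 4.36e-32, adjusted p = 0.00256 with an estimated correlation). Havcr1 (ENSRNOG00000007243), known as kidney injury molecule 1, stood at 52.6 ± 29.4 FPKM against 1.21 ± 0.397, a log2 difference of 4.48 ± 0.23 (SE, adjusted p = 1.25e-16), Lcn2 (ENSRNOG00000013973), a siderophore-binding injury marker, at 153 ± 72.2 against 6.85 ± 1.1, and Clu, clusterin, at 818 ± 578 against 58.4 ± 2.07. Mmp7 (ENSRNOG00000010507), a secreted metalloprotease, was at 17.9 ± 8.33 against 0.0425 ± 0.0566, a ratio of 389 with a 95% counting interval of 133 to 1890. The other genes among the 8 largest rises were Il19 and Il24, cytokines of the IL-10 family, Socs3, an inhibitor of cytokine signalling, and Fgg, a fibrinogen chain.

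Immune genes rose with them at PND15. Of 24 macrophage and dendritic cell markers 23 rose and 0 fell (adjusted over the list alone 23 and 0; camera adjusted p = 5.34e-31, adjusted p = 0.00619 with an estimated correlation). C1qa stood at 48.7 ± 19.5 against 12 ± 1.88 FPKM and Gpnmb 6.68-fold. Lymphocyte markers rose in 11 of 15 and fell in 0 (adjusted over the list alone 14 and 0; camera adjusted p = 2.94e-09, adjusted p = 0.0307 with an estimated correlation). Cd8a stood at 2.92-fold. Cytokine and chemokine genes rose in 18 of 25 and fell in 1 (adjusted over the list alone 18 and 1; camera adjusted p = 6.19e-17, adjusted p = 0.00619 with an estimated correlation). Cxcl1 stood at 7.31-fold and Il1b at 5.38-fold. Complement and coagulation genes rose in 15 of 25 and fell in 0 (adjusted over the list alone 16 and 1; camera adjusted p = 8.28e-15, adjusted p = 0.00619 with an estimated correlation). Cfi, a complement regulator, stood at 9.16-fold. Antigen presentation and interferon genes rose in 15 of 29 and fell in 0 (adjusted over the list alone 19 and 0; camera adjusted p = 3.57e-11, adjusted p = 0.0559 with an estimated correlation) and matrix genes in 11 of 29 and fell in 0 (adjusted over the list alone 12 and 0; camera adjusted p = 1.08e-08, adjusted p = 0.17 with an estimated correlation). Timp1, an inhibitor of metalloproteases, stood at 3.77-fold.

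Genes of tubule function fell at PND15. Proximal tubule transport and endocytosis genes fell in 21 of 31 and rose in 0 (adjusted over the list alone 23 and 0, median -0.54 log2; camera adjusted p = 1.48e-11, adjusted p = 0.0916 with an estimated correlation). Proximal tubule metabolism genes fell in 18 of 30 and rose in 1 (adjusted over the list alone 19 and 1; camera adjusted p = 6.13e-10, adjusted p = 0.0942 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 28 and rose in 0 (adjusted over the list alone 18 and 0; camera adjusted p = 1.83e-11, adjusted p = 0.0942 with an estimated correlation). Slc22a6 and Slc22a8, carriers of organic anions, stood at 0.598 and 0.613 times WT. Hnmt was at 7.81 ± 4.75 against 23.6 ± 3.32 FPKM and Egf at 13.5 ± 5.97 against 38.9 ± 14.2; with Klk1c9, Slco1a6, Dnase1, Sbspon and Cdo1 these were among the 8 largest falls. Dnase1 and Cdo1, with limma adjusted p of 0.0312 and 0.00834, lost the call without Homo replicate 1 or 3. Dnase1 lost it also without WT replicate 1, 2 or 3, with voom and with only the ages compared. Oxidative phosphorylation genes fell in 25 of 30 and rose in 0 (adjusted over the list alone 29 and 0; camera adjusted p = 3.42e-13, adjusted p = 0.169 with an estimated correlation), 14 of them with TPM, beside a mitochondrial share of reads of 6.19 ± 0.999% against 8.41 ± 0.828%. Intercalated cell genes fell in 11 of 20 and rose in 0 (adjusted over the list alone 15 and 0; camera adjusted p = 6e-09, adjusted p = 0.0818 with an estimated correlation). Atp6v0a4, a proton pump subunit, stood at 0.596 times WT.

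Lists near Xdh itself split at PND15. Of 19 purine degradation and salvage genes 2 rose and 2 fell (adjusted over the list alone 3 and 2); its median of -0.03 log2 turned to 0.08 with TPM (camera adjusted p = 0.747). Gda, guanine deaminase, which makes xanthine from guanine, rose 7.35-fold, and Nt5e, which makes adenosine outside cells, stood at 0.624 times WT. Of 9 molybdenum cofactor genes 1 rose and 2 fell (adjusted over the list alone 1 and 2; camera adjusted p = 0.186): Mocos, the sulfurase that activates xanthine dehydrogenase, rose 2.54-fold, and Suox, sulfite oxidase, stood at 0.658 times WT. The superoxide and antioxidant list split into 6 higher and 6 lower of 23 (adjusted over the list alone 6 and 7; camera adjusted p = 0.811; its median of -0.09 turned to 0.02 with TPM), with Cybb and Ncf1, parts of the phagocyte oxidase, at 2.86-fold and 4.1-fold. Cell cycle genes were called in 0 of 35 (adjusted over the list alone 0; camera adjusted p = 0.808). In all, 2702 genes changed, 1479 up and 1223 down, 321 and 63 of them at least 2-fold. TPM called 2366 up and 722 down, and the count was 1688 without Homo replicate 1 and 1722 without Homo replicate 3.

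At PND21 Homo (n = 3) and WT (n = 3) differed in many lists. Tubular injury genes rose in 29 of 31 and fell in 0 (adjusted over the list alone 29 and 0, median 2.27 log2; camera adjusted p = 3.96e-26, adjusted p = 0.00815 with an estimated correlation). Havcr1 stood at 175 ± 69.7 FPKM against 1.06 ± 0.353, a log2 difference of 6.36 ± 0.26 (SE, adjusted p = 6.5e-20), Fgg (ENSRNOG00000025074) at 87.5 ± 7.48 against 0.501 ± 0.129 and Lcn2 at 373 ± 106 against 8.06 ± 2.44. Reg3g (ENSRNOG00000006579), an antimicrobial lectin, was at 28.1 ± 6.69 FPKM in Homo and at 0 reads in WT, at least 294-fold higher (floor of 3 reads over the group). Mmp7 was at 36.3 ± 11.6 against 0.0437 ± 0.0386, a ratio of 809 with a 95% counting interval of 224 to 6680. Il19, Socs3 and Sfn, a cell cycle regulator of the 14-3-3 family, completed the 8 largest rises.

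All 24 macrophage and dendritic cell markers rose at PND21 (adjusted over the list alone 24 and 0, median 2.25 log2; camera adjusted p = 1.42e-26, adjusted p = 0.0128 with an estimated correlation). Gpnmb stood at 31.5-fold and C1qa at 7.22-fold. Lymphocyte markers rose in 13 of 15 and fell in 0 (adjusted over the list alone 14 and 0; camera adjusted p = 5.13e-09, adjusted p = 0.0352 with an estimated correlation). Cd3e stood at 14.6-fold and Cd4 at 5.81-fold. Neutrophil and mast cell markers rose in 7 of 12 and fell in 0 (adjusted over the list alone 7 and 0; camera adjusted p = 7.6e-05, adjusted p = 0.0419 with an estimated correlation). S100a9 stood at 27.8-fold. Cytokine and chemokine genes rose in 20 of 25 and fell in 1 (adjusted over the list alone 22 and 1; camera adjusted p = 1.48e-15, adjusted p = 0.00815 with an estimated correlation). Cxcl1 stood at 41.4-fold. Complement and coagulation genes rose in 19 and fell in 2 of 25 (adjusted over the list alone 20 and 2; camera adjusted p = 4.19e-14, adjusted p = 0.00815 with an estimated correlation). C3 stood at 29.3-fold. Matrix genes rose in 21 of 29 and fell in 0 (adjusted over the list alone 24 and 0, median 1.07 log2; camera adjusted p = 1.41e-09, adjusted p = 0.141 with an estimated correlation). Timp1 rose 9.65-fold and Tgfb1, a profibrotic growth factor, 2.55-fold. Genes of p53 and cell death rose in 10 and fell in 3 of 20 (adjusted over the list alone 10 and 3; camera adjusted p = 0.0282, adjusted p = 0.14 with an estimated correlation). Cdkn1a, which halts the cell cycle, stood at 3.84-fold.

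Function genes of the proximal tubule, the loop of Henle and intercalated cells fell at PND21. Egf was at 6.27 ± 3.76 against 75 ± 2.58 FPKM (log2 difference -3.56 ± 0.32 SE, adjusted p = 8.86e-11), Hnmt at 9.38 ± 0.724 against 83.8 ± 12.6, and Slc4a1, an anion exchanger of intercalated cells and red cells, at 8.7 ± 4.78 against 59.6 ± 10.3. Klk1c2, a kallikrein, was at 5.39 ± 1.43 FPKM in WT and at 0 reads in Homo, at least 66.9-fold lower; Klk1c9, Cyp1a1, Slco1a6 and Oacyl were the others of the 8 largest falls. Intercalated cell genes fell in 18 of 20 and rose in 0 (adjusted over the list alone 18 and 0, median -1.23 log2; camera adjusted p = 1.47e-11, adjusted p = 0.0419 with an estimated correlation). Urate and organic anion transporters fell in 15 of 19 and rose in 0 (adjusted over the list alone 16 and 0; camera adjusted p = 1.59e-08, adjusted p = 0.042 with an estimated correlation). Slc22a7 stood at 0.216 times WT. Proximal tubule transport genes fell in 23 of 31 and rose in 0 (adjusted over the list alone 23 and 0; camera adjusted p = 5.77e-10, adjusted p = 0.116 with an estimated correlation). Slc34a1, the phosphate carrier, stood at 685 ± 299 against 2030 ± 62.1 FPKM. Proximal tubule metabolism genes fell in 22 and rose in 1 of 30 (adjusted over the list alone 24 and 1; camera adjusted p = 2.96e-09, adjusted p = 0.116 with an estimated correlation). Miox, which breaks down inositol, stood at 0.262 times WT. Loop of Henle genes fell in 12 and rose in 1 of 17 (adjusted over the list alone 12 and 1; camera adjusted p = 2.75e-06, adjusted p = 0.119 with an estimated correlation).

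Endothelial markers fell in 10 of 18 and rose in 0 at PND21 (adjusted over the list alone 11 and 0; camera adjusted p = 7.83e-05, adjusted p = 0.132 with an estimated correlation). Plvap stood at 0.423 times WT. Podocyte markers fell in 13 and rose in 2 of 19 (adjusted over the list alone 13 and 3; camera adjusted p = 0.00261, adjusted p = 0.177 with an estimated correlation). Podxl stood at 0.545. Oxidative phosphorylation genes fell in 29 of 30 and rose in 0 (adjusted over the list alone 29 and 0, median -0.58 log2; camera adjusted p = 8.4e-14, adjusted p = 0.146 with an estimated correlation), 28 of them with TPM, beside a mitochondrial share of reads of 7.25 ± 0.274% against 10.7 ± 0.547%. Fatty acid oxidation genes fell in 17 and rose in 1 of 28 (adjusted over the list alone 19 and 1; camera adjusted p = 4.4e-07, adjusted p = 0.177 with an estimated correlation). Glutathione and NRF2 genes fell in 13 and rose in 4 of 27 (adjusted over the list alone 13 and 4; camera adjusted p = 0.00749, adjusted p = 0.323 with an estimated correlation). Gclc stood at 171 ± 8.5 against 984 ± 298 FPKM. Erythroid and blood genes fell in 11 of 12 and rose in 0 (adjusted over the list alone 12 and 0, median -1.57 log2; camera adjusted p = 5.41e-05, adjusted p = 0.171 with an estimated correlation). Ahsp, a globin chaperone, stood at 0.211 times WT.

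Of the lists near Xdh at PND21, purine degradation and salvage genes rose in 4 and fell in 3 of 19 (adjusted over the list alone 6 and 3; camera adjusted p = 0.581), with Gda at 11.3-fold and Nt5e at 0.565 times WT. Molybdenum cofactor genes rose in 1 and fell in 4 of 9 (adjusted over the list alone 1 and 4; camera adjusted p = 0.0363, adjusted p = 0.245 with an estimated correlation). Mocos stood at 2.47-fold. The superoxide and antioxidant list rose in 8 and fell in 9 of 23 (adjusted over the list alone 8 and 9; camera adjusted p = 0.824). Of the other lists of tissue that a dissected cortex can carry, adrenal had 0 of 7 called, fat tissue 1 higher of 12, liver 2 higher of 11, skeletal and smooth muscle 2 higher of 7, and the osmotic and inner medulla list 2 lower of 14, none past camera (adjusted p = 0.928, 0.685, 0.21, 0.14 and 0.386); adjusted over the list alone these counts were 0, 1, 2, 2 and 2. The liver list had a median of -0.01 log2 and a mean of 0.48. In all, 5721 genes changed, 2861 up and 2860 down, 898 and 556 of them at least 2-fold. TPM, which moved the median of all genes by 0.17 log2, called 4797 up and 1619 down.

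**Figure D2:**
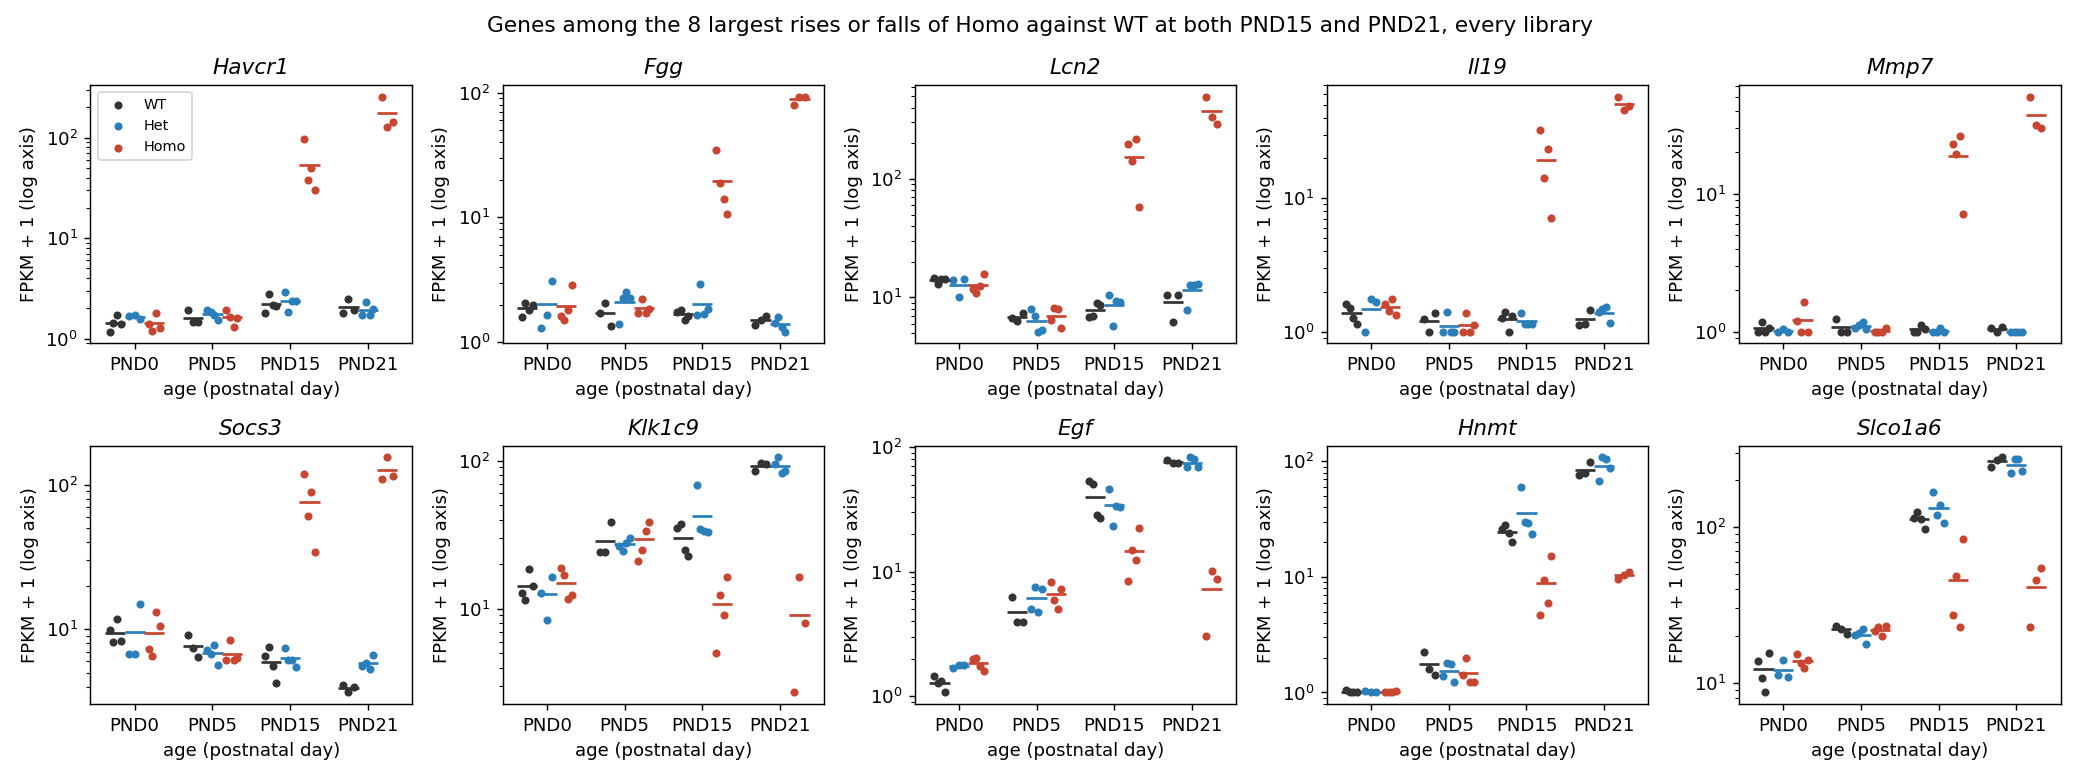
FPKM + 1 on a log axis (y) at each postnatal day (x) for the 10 genes among the 8 largest rises or falls of Homo against WT at both PND15 and PND21; points are libraries and bars are group means, coloured by labelled genotype. Havcr1 averages 52.6 FPKM in Homo at PND15 and 175 at PND21 against 1.21 and 1.06 in WT, and Egf averages 6.27 in Homo at PND21 against 75 in WT.

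**Figure D3:**
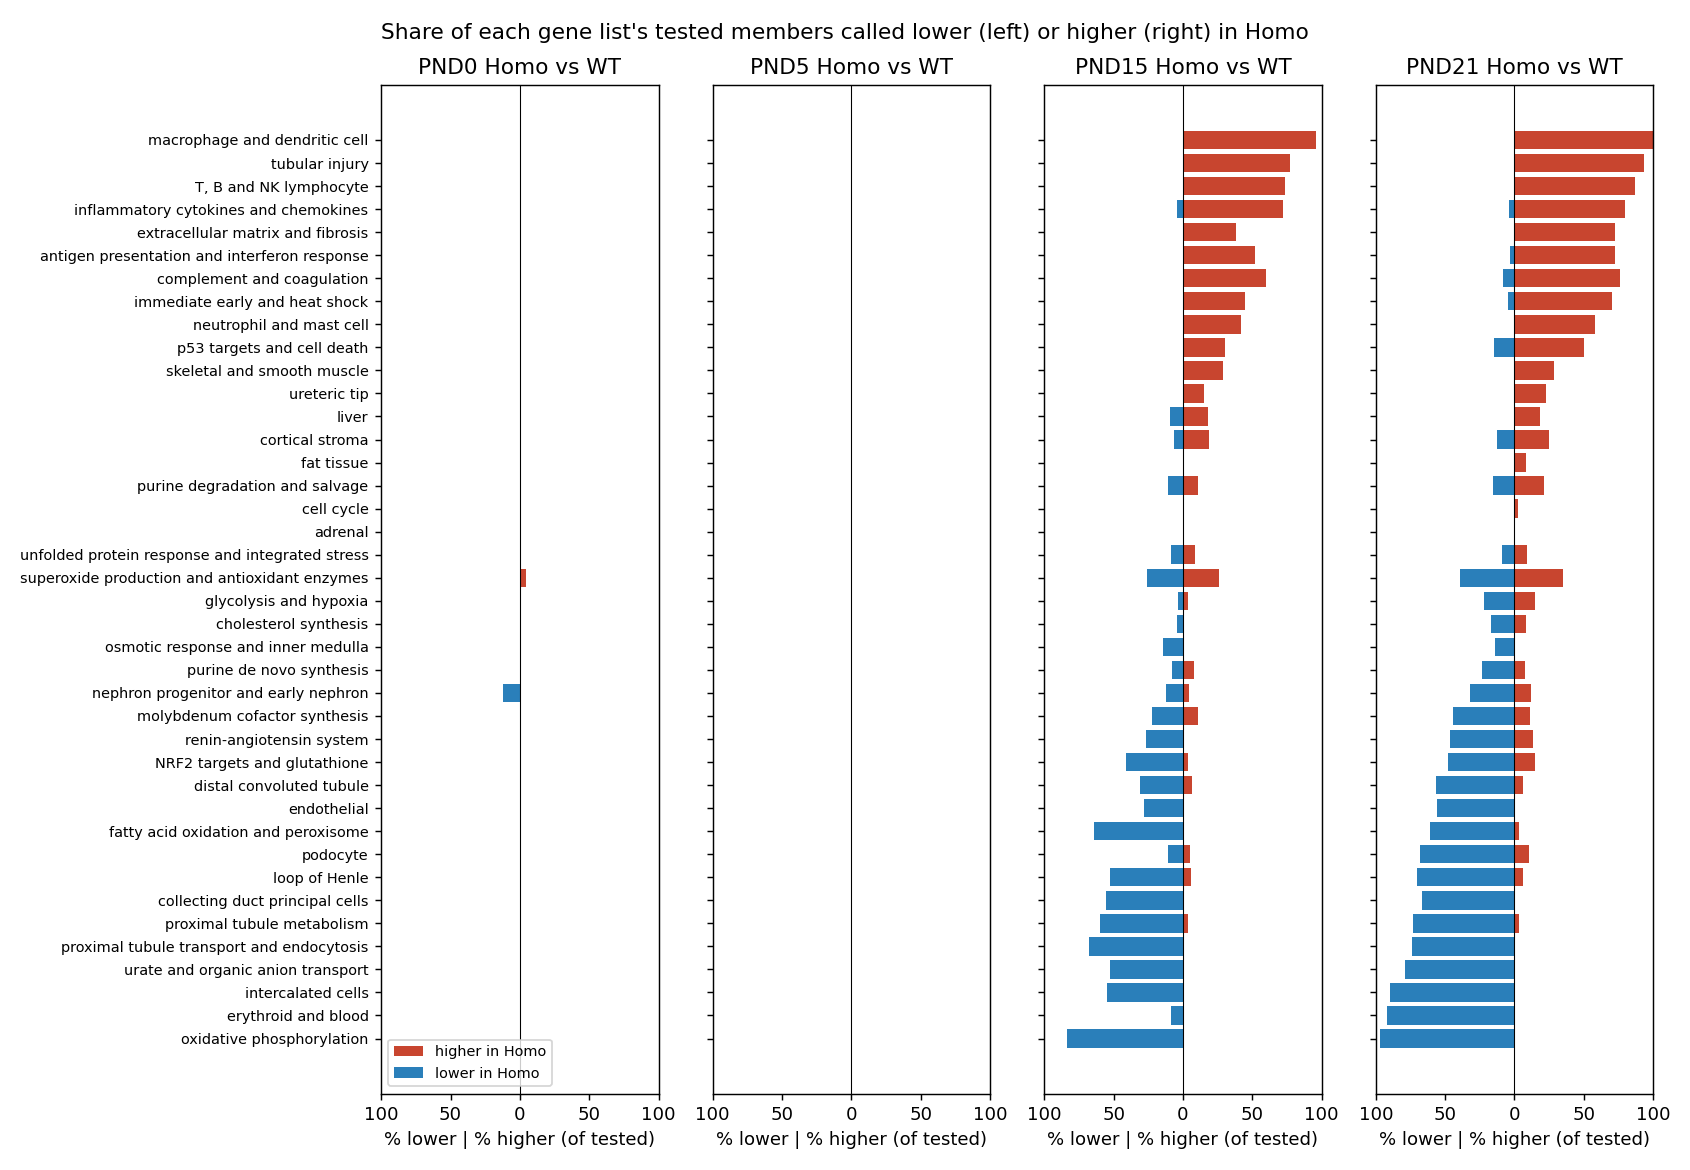
Percent of each gene list's tested members called lower (left, blue) or higher (right, red) in Homo against WT, 1 panel per postnatal day, x axis from 100% lower to 100% higher. At PND21 all 24 macrophage and dendritic cell markers are called higher and 29 of 30 oxidative phosphorylation genes lower; at PND15 oxidative phosphorylation has 25 called lower, or 14 with TPM.

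The difference between Homo and WT changed with age for 4179 genes (limma F test of PND5, PND15 and PND21 against PND0; 5788 at an unadjusted p under 0.05). Havcr1 had log2 differences of -0.02 ± 0.23 (SE) at PND0, 0.01 ± 0.24 at PND5, 4.48 ± 0.23 at PND15 and 6.36 ± 0.26 at PND21 (adjusted p of the change 3.76e-17). Of Reg3g, Mmp7, Il24, Fgg, Il19, Lcn2, Cfi and Clu, also among the 10 genes with the smallest p, none was called at PND0 or PND5, where the largest difference was 0.37 ± 0.22 log2 (SE), for Clu at PND0, and each rose at both later ages, from 1.72 ± 0.16 log2 for Reg3g at PND15 upward.

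A maturity score set genes that rise with age against genes that fall, both chosen in Het libraries alone. In WT it went from 0.14 ± 0.14 at PND0 (n = 4) to 1.14 ± 0.11 at PND5 (n = 3), 2.72 ± 0.15 at PND15 (n = 4) and 3.88 ± 0.22 at PND21 (n = 3). Homo scored lower at PND15, at 2.15 ± 0.26 (n = 4; difference -0.56, two-sided exact permutation p = 0.0286, adjusted over 4 ages 0.0571), and at PND21, at 2.63 ± 0.23 (n = 3; difference -1.25, exact permutation p = 0.1, the smallest that 3 against 3 can give, adjusted 0.133). At PND5 the scores were 1.14 ± 0.2 and 1.14 ± 0.11 (exact permutation p = 0.971, adjusted 0.971). At PND0 libraries labelled Homo scored higher, 0.53 ± 0.08 against 0.14 ± 0.14 (n = 4 each; exact permutation p = 0.0286, adjusted 0.0571). None of the 4 passed after adjustment.

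**Figure D4:**
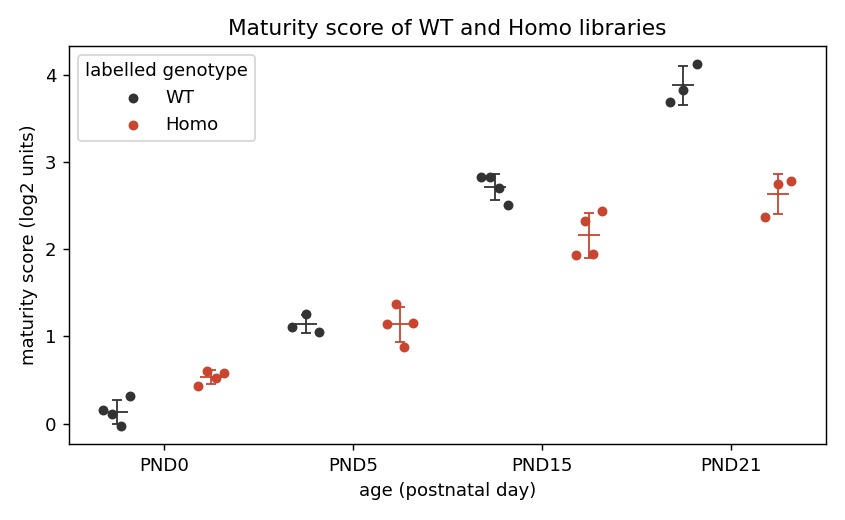
Maturity score (y axis, log2 units: mean log2(FPKM + 1) of 500 genes that rise minus that of 500 genes that fall from PND0 to PND21 in Het libraries) at each postnatal day (x axis) in WT and Homo libraries, labelled genotype; points are libraries, bars the mean and SD. WT averages 3.88 at PND21 and Homo 2.63, while at PND5 both average 1.14.

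In Het against WT few genes were called. limma called 1 gene at PND0 (1542 at an unadjusted p under 0.05), 0 at PND5 (254), 2 at PND15 (916) and 0 at PND21 (895); voom called 0, 0, 2 and 0. Of 40 lists, 7, 4, 13 and 11 passed camera at these ages, and 0 at each with an estimated correlation. At PND15 the gene named by rule was Mamdc2, at 2.08 ± 0.468 against 5.41 ± 2.04 FPKM (n = 4 each, log2 difference -1.02 ± 0.19 SE, adjusted p = 0.0326). The other was Pgm2l1 (log2 difference -0.69 ± 0.13 SE, adjusted p = 0.0326), and at PND0 Fgf20 was lower in libraries labelled Het (-0.69 ± 0.11 SE, adjusted p = 0.00524); both were chosen after their values were seen. Mamdc2 lost its call without WT replicate 3 or 4 or Het replicate 1, 2 or 3, and the PND15 count was 1 without WT replicate 2, Het replicate 1 or Het replicate 3 and 0 without WT replicate 3, WT replicate 4 or Het replicate 2. At PND0 the count was 79 without Het replicate 1, 7 without Het replicate 3, 3 without WT replicate 1, 2 without WT replicate 4 and 0 without WT replicate 3 or Het replicate 2, and at PND21 it was 1 without WT replicate 3, Het replicate 1 or Het replicate 3.

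Homo was also compared with Het, a contrast without the WT groups; the Homo libraries are those compared with WT. At PND15 tubular injury genes rose in 29 of 31 and fell in 0 (adjusted over the list alone 29 and 0; camera adjusted p = 7.84e-29, adjusted p = 0.00512 with an estimated correlation), and at PND21 in 28 and fell in 0 (adjusted over the list alone 29 and 0; camera adjusted p = 3.16e-24, adjusted p = 0.0097 with an estimated correlation). Havcr1 stood at 52.6 ± 29.4 FPKM against 1.37 ± 0.447 at PND15 (n = 4 each) and at 175 ± 69.7 (n = 3) against 0.932 ± 0.282 (n = 4) at PND21. Macrophage and dendritic cell markers rose in 23 of 24 at PND15 and in 24 at PND21 (adjusted over the list alone 23 and 24; camera adjusted p = 2.58e-24 and 3.16e-24; adjusted p = 0.0205 at both ages with an estimated correlation). Urate and organic anion transporters fell in 12 of 19 at PND15 (adjusted over the list alone 13; camera adjusted p = 3.07e-10, adjusted p = 0.0308 with an estimated correlation). The largest rises were Havcr1, Mmp7 and Lcn2 at PND15 and Havcr1, Fgg and Il19 at PND21, and the largest falls Dnase1, Hnmt and Klk1c9 at PND15 and Klk1c9, Egf and Hnmt at PND21. Dnase1 at PND15 rests in part on Het replicate 2, at 111 FPKM: its log2 difference of -2.16 (adjusted p = 0.000892) was -1.53 (adjusted p = 0.0122) without that library, and its call was lost with only the groups compared (adjusted p = 0.0531). In all, 3993 genes changed at PND15, 2104 up and 1889 down, and 6659 at PND21, 3323 up and 3336 down. TPM, which moved the medians by 0.14 and 0.23 log2, called 3852 up and 1072 down at PND15 and 6167 up and 1694 down at PND21, and with only the groups compared the PND15 count was 2393. At PND21 all Homo animals and 1 of the 4 Het animals bear numbers of 100 and above, so this contrast runs mostly along the numbers; with a term for them, chosen after seeing the data, 4892 genes were called. At PND5 limma called 0 genes (290 at an unadjusted p under 0.05, voom 0). At PND0 it called 1, AY172581.16 (-1.58 ± 0.28 log2, adjusted p = 0.0435, named after its values were seen), between libraries labelled Homo and Het; the count was 2 without Het replicate 1 and 0 without Het replicate 2, Homo replicate 2 or Homo replicate 4.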

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

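All tests that weigh an explanation in this part were chosen after the results they explain were seen, as were the permutations of the maturity score over pairs of ages.

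In 155 groups of 4 libraries, over the genes named and the mitochondrial share, 12 held a library far from the others, and chance alone does so in about 1 in 20 groups. The mitochondrial share of reads was 11.8% in PND21_Het replicate 2, against 10.5% to 10.7% in the others of its group. In PND0_WT replicate 4, Dpt stood at 7.64 FPKM (others 0.823 to 1.13), Nox4 at 11.8 (5.84 to 6.51) and Spink1 at 3.27 (0.867 to 1.05). In PND0_WT replicate 3, Fgf20 stood at 2.5 FPKM (1.55 to 1.6) and Siah1 at 39.1 (23.5 to 25.9). In PND15_WT replicate 4, Cybb stood at 5.85 FPKM (4.12 to 4.38) and Gclc at 289 (341 to 352), and in replicate 3 of that group Sbspon at 39 (31.8 to 32.9). Among PND15_Het libraries, Dnase1 stood at 111 FPKM in replicate 2 (15.3 to 24.6) and Klk1c9 at 67.5 in replicate 1 (31.9 to 33.7). Mmp7 stood at 0.0676 in replicate 3, with the others at 0. That Mmp7 value is 1 read, and with the others at 0 any read would have been flagged.

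The mean maturity score of Homo lay above that of WT at PND0 and below it at PND15 and PND21. The difference moved by -0.96 log2 units from PND0 to PND15 (two-sided exact permutation p = 0.000408, the smallest that 4900 relabellings give, adjusted over 2 tests 0.000816), and by -1.64 from PND0 to PND21 (exact permutation p = 0.00143, the smallest that 1400 relabellings give). Both rest on PND0 labels that Xdh does not follow. Labels were permuted within each age, so these p-values test for no genotype difference at either age. They do not test whether the difference changed between ages, and no test within a single age passed after adjustment. Among the 10 genes whose difference between Homo and WT changed most with age, adjusted p were 3.76e-17 for Havcr1, 1.52e-16 for Reg3g, 1.55e-15 for Mmp7, 2.5e-15 for Il24, 3.93e-14 for Fgg, 8.13e-14 for Il19, 8.84e-14 for Lcn2, 1.15e-13 for Cfi and 1.26e-13 for Clu (limma F test).

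Xdh was high in PND0_Homo replicate 3 and replicate 4 and in PND0_Het replicate 2. An exchange of the 2 Homo labels with WT libraries of the same age is argued against, since it needs libraries labelled WT at the level of Homo, and the lowest of these held 1.6 FPKM against 1.09 at most in the other PND0 and the PND5 Homo libraries. For the Het library the level of the WT libraries cannot settle an exchange, since 1 of these 4 lay at or below the higher of the other 2 Het libraries. The levels of the 3 libraries themselves argue against an exchange with WT libraries alone. The lowest of the 3 held 11.7 FPKM, and the libraries labelled WT at PND0 held 3.78 at most. Animals of PND15 or older are argued against too: the highest of the 3 on the first principal component lay at -31.2, and the lowest library of PND15 and PND21 at 9.34. The 3 come from animals with consecutive numbers below 100, while the other 2 Homo and all 4 WT animals of PND0 are numbered 100 or above. Numbers below 100 as a block are argued against as the whole cause, because the other 2 Het animals lie below 100 as well, 1 of them next to the 3, and the higher of these 2 held 1.87 FPKM. A litter or handling shared by the 3 alone stays open, since the meaning of the numbers is not given in the sources used here. A glucocorticoid response of the animals may play a part: over 33 libraries of the later ages Xdh followed 23 glucocorticoid target genes within groups with r = 0.43 (permutation p = 0.00415, adjusted over 2 lists 0.00491) and Spearman rho = 0.53 (permutation p = 0.00212), and r = 0.3 (permutation p = 0.0443) without the 2 farthest libraries, with 0.61, 0.33 and 0.6 within PND5, PND15 and PND21. The correlation does not give the size of such a part. PND15_Het replicate 2, the later library farthest from its group in the list mean (5.9), held 13.2 FPKM of Xdh. The other PND15 Het libraries had list means of 5 to 5.31 and held 8.95 to 11.2. The list was written after the 3 PND0 libraries were seen. Its mean was 5.99, 6.6 and 6.32 in them, against 5.43 at most in the other 8 PND0 libraries. Other errors of labels stay open.

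Genes called at PND21 in Homo were set against the level of a younger WT kidney. Delay alone is argued against for the higher genes, of which 47.5% had every Homo library above every WT library of all 4 ages. For the lower genes, with 15.9% below every WT library, delay and other causes cannot be told apart, since most fall within the range of younger WT kidneys. Scaling is argued against for changes of 2-fold or more. The widest ratio of summed FPKM between a Homo and a WT library of PND21 was 0.3 log2. Less 2 SE, 99.4% of the 898 higher and 98.6% of the 556 lower genes lay beyond it. With TPM 97.1% of these lower genes stayed called. The genes were picked as called and 2-fold or more, so shares this high beyond 0.3 log2 were largely set by that choice. Of all genes called, 56% of the higher and 47.3% of the lower lay beyond it. For the 1963 higher genes under 2-fold scaling and a rise cannot be told apart: 100% stayed called with TPM, but TPM moves the genes up in Homo, by 0.17 log2 at the median, and could not have ended these calls. Of the 2304 lower genes under 2-fold 46.8% stayed, so scaling may account for part of them.

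Immune and matrix markers were higher at PND21 in Homo. A lower share of tubule cells alone is argued against, because 23 endothelial and podocyte markers were called lower and 2 higher, of 37. These counts are from the main scaling, so falls under 2-fold among them may in part come from scaling. Neither list passed camera with an estimated correlation, which limits this argument. More red cell RNA in the tissue is argued against, because 11 of 12 erythroid markers were lower. These markers do not measure white cells, so blood as a source of immune markers stays open and was not tested. The growth or entry of immune and stromal cells stays open as the biological explanation and was not tested.

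Other splits of the same libraries were counted for each comparison of genes. For Homo against WT at PND15 only the real split called as many genes (1 of 35 splits, 2702 genes, highest other 1479). The same held for Homo against Het at PND15 (1 of 35, 3993, 2260) and PND21 (1 of 35, 6659, 4721). It held for WT PND5 against PND0 (1 of 35, 1923, 1636), PND15 against PND5 (1 of 35, 4215, 1651) and PND21 against PND15 (1 of 35, 2786, 1307). It also held for the change of the difference with age (1 of 100, 4179, 3441). These are the smallest shares that 35 or 100 splits can give, and they were not adjusted over the comparisons. Chance is therefore not excluded by them. At PND21 Homo against WT has 10 splits, too few for a share under 0.05 (1 of 10; 5721, highest other 1). Nor can chance be excluded at PND0, where other splits reached the real count. This was so for Homo against WT (3 of 35, 57, 439), Het against WT (18 of 35, 1, 424) and Homo against Het (15 of 35, 1, 2331). Chance cannot be excluded for Het against WT at PND15 either (7 of 35, 2, 39). Where 0 genes were called every split reaches as many, so the count decides nothing: at PND5 for Homo against WT (35 of 35; 0, 15), Het against WT (35 of 35; 0, 1) and Homo against Het (35 of 35; 0, 1), and at PND21 for Het against WT (35 of 35; 0, 1.3e+02). The splits at PND0 that call several times the real count point to a structure of the samples other than genotype: the 2331 genes come from the split that parts PND0_Homo replicates 3 and 4 and PND0_Het replicate 2 from the rest. The split with 1.3e+02 at PND21 parts the 4 animals numbered below 100 from the 3 of 100 and above. Those below 100 are WT replicate 3 and Het replicates 2, 3 and 4. The split with 4721 parts the same 3 Het libraries from Het replicate 1 and Homo. It is the real split with Het replicate 1 moved, so genotype and the numbers cannot be told apart in it. All PND21 Homo animals are numbered 100 or above, so Homo against Het at PND21 runs mostly along this block. For Homo replicate 1 this place is assumed, since its title has another prefix. With a term for the block 4892 of 16283 genes were called, 2501 up and 2391 down.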

How the results depend on the processing

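The settings with the 3 high PND0 libraries, or PND15_Het replicate 2, set aside, and the wider term for animal numbers, were chosen after seeing the data. No paired analysis was possible because replicate numbers only follow the order of the records. The fit of only the ages compared was not run for the test of change with age, which uses the same libraries, and the planned term for animal numbers was run only where both groups hold numbers on both sides of 100, the PND5 comparisons and Het against WT at PND21. The wider term takes in PND0 and PND21, where at least 1 group does. The cause was not tested where none is given.

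Counts for Homo against WT at PND0 (57) became 34 with a pseudocount of 0.1, 165 with TPM, 456 with array weights, 103 with voom, 0 with only the ages compared, 0 with only the groups compared, 21 with the 3 libraries set aside, 1.2e+02 with PND15_Het replicate 2 set aside and 12 with the wider term for animal numbers; of the 21, 6 were shared. At PND5 (0) they became 2 with no filter, 1 with ages, 4 with groups and 1 with the 3 set aside. Het against WT at PND0 (1) became 12 with no filter, 0 with a mean of at least 5 FPKM, 0 with array weights, 0 with voom, 2 with groups, 0 with the 3 set aside and 0 with the wider term. It became 2 at PND5 (0) with no filter. At PND15 (2) it became 0 with no filter, a mean of at least 5 FPKM, ages, groups, the 3 set aside or PND15_Het replicate 2 set aside, and 4 with array weights. At PND21 (0) it became 3 with no filter and 3 with array weights. Homo against Het at PND0 (1) became 0 with no filter, array weights, groups or the 3 set aside, at PND5 (0) 1 with no filter and 1 with the 3 set aside, and at PND15 (3993) 2393 with groups, which hold fewer libraries. WT PND5 against PND0 (1923) became 4121 with array weights and 1062 with groups, and PND21 against PND15 (2786) 5042 with TPM. At PND21 the wider term called 5637 in Homo against WT (5721) and 4892 in Homo against Het (6659), and 3706 changed with age (4179). The maturity difference at PND5 was 0 with 500 and with 100 genes per direction, with another sign below 2 decimals.

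List tests past camera at PND0 (13) became 0 with an estimated correlation and 3 with fry, at PND5 (1) 0 and 0, at PND15 (22) 5 and at PND21 (24) 8 with an estimated correlation. Between WT ages they became 2 and 9 (of 14) from PND0 to PND5 and 0 with an estimated correlation at both later steps.

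Xdh at PND0 turned to -0.47 log2 with array weights (limma adjusted p = 0.618) in Homo against WT. The 3 libraries were picked for their high Xdh, so Xdh itself is not tested by setting them aside: its turns there, to -1.14 in Homo against WT and -0.4 in Het against WT, and its smaller p, as in Homo against Het at PND5 (-1.24), follow from that choice. Setting them aside left the log2 differences of Homo against WT at PND5 (-1.65) and PND15 (-1.41) unchanged. The smaller p at these ages came through the spread shared by all groups. With the wider term Xdh was -1.14 (limma adjusted p = 0.439) in Homo against WT, -2.66 (0.272) in Het against WT and 1.52 (0.439) in Homo against Het. These values are no separate check. At PND0 only Homo holds numbers on both sides of 100, so Homo against WT again rests on Homo replicates 1 and 2. All PND0 Het animals are numbered below 100 and all WT animals above it, so Het against WT cannot be parted from the numbers. From PND5 to PND15 in WT the call of Xdh was lost with a pseudocount of 0.1 (1.89, adjusted p = 0.0665) and TPM (1.71, adjusted p = 0.056). Xdh kept the call with array weights (0.00135), voom (0.0486), ages (1.53e-05), groups (1.29e-05), no filter (0.0477) and a mean of at least 5 FPKM (0.0332). It was called in Homo against WT at PND15 (-1.41) with array weights (adjusted p = 0.00783), ages (0.00352) and groups (0.012), at PND5 (-1.65) with ages (0.0212) and groups (0.0277), and at PND21 (-0.57) with ages (0.0289) and groups (0.00823). In Homo against Het it was called at PND15 (-0.91) with ages (0.0109) and groups (0.0387). From PND15 to PND21 in WT (0.59) it was called with groups (0.00292).

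Leaving out 1 library in turn gave 2 to 167 genes in Homo against WT at PND0, 0 to 1 at PND5, 1688 to 3197 at PND15 and 4423 to 5370 at PND21. It gave 0 to 79 in Het against WT at PND0, 0 to 3 at PND15 and 0 to 1 at PND21, and 0 to 2 in Homo against Het at PND0. It gave 823 to 2247 in WT PND5 against PND0 and 1486 to 2646 in PND21 against PND15. The maturity difference at PND5 ranged from -0.08 to 0.08. Division by median ratios moved the median of Homo against WT at PND21 by 0.00098 log2, so it is no test of stability. Of the 691 results for single named genes, 635 kept direction and call with TPM and 665 with voom, and with groups 622 of the 682 that it tested. In the simulated data 86% to 93% of 2-fold changes were recovered. Genes were drawn there independently, each with the same spread in all groups, and depth was not varied. The share recovered therefore does not carry over to the real libraries and does not show what limited their calls.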
